A study of Mus musculus with 90 samples.

How the data were processed

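RNA of primary skeletal myoblasts from MyoD-/- mice was measured on 3 Affymetrix chip designs, MG_U74Av2, MG_U74Bv2 and MG_U74Cv2, in 30 arrays each. The 90 arrays came from 3 cultures, named 1999, P6 and P10 in the titles, each sampled at 0h, 6h, 12h, 18h, 24h, 36h, 48h, 3d, 4d and 7d. The labels do not state what the culture names stand for, and every sample carries the same genotype. Cells grew in Ham's F10 medium with fetal bovine serum and basic fibroblast growth factor and were then fed a differentiation medium of DMEM with horse serum.

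The authors prepared biotinylated cRNA and summarised each array with MAS5. The deposited values are intensity, that is linear MAS5 signal scaled per array, and the software version and the scaling target are not stated. Values ran from 0.2 to 236077 on MG_U74Av2, from 1.1 to 502575 on MG_U74Bv2 and from 1.4 to 1010450 on MG_U74Cv2. Mean signal per array lay between 2174 and 2532, between 1946 and 2142 and between 2442 and 3009 on these chips in that order. Probe-level files and detection calls were not used here. Precision is limited by the number of arrays, 3 per group.

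Signals were taken to log2 after adding the 25th percentile of the chip table (119.8, 270.1 and 213.0). The 66 control probe sets of each chip were left out, and a probe set was tested when at least 3 of the 30 arrays exceeded the chip median, which left 7423, 8254 and 8630 probe sets. Chip annotation gave 1 gene symbol to 19865 of the 24307 tested probe sets, for 12373 genes. Probe sets with several symbols or none were tested but not named. A gene was represented by 1 probe set, taken from MG_U74Av2 before MG_U74Bv2 before MG_U74Cv2, with the highest mean signal among those without a suffix mark for shared or incomplete probe design.

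Each later time was compared with 0h, and each time with the one before it, in a limma model of time fitted per chip over all 30 arrays. The moderated tests were two-sided. P values were adjusted by the Benjamini-Hochberg method over the 3 chips together, and an adjusted p under 0.05 counted as passing. A joint test over all times used the same model. Cultures were compared in a model with time and culture. The change from the early phase (0h, 6h and 12h) to the late phase (3d, 4d and 7d) was compared between cultures as an interaction. Errors given with log2 fold changes are standard errors of the model, and errors given with mean signals are standard deviations over 3 samples. Simulated data took the mean of the 0h arrays and the residual spread of a fit with culture as a block, without differences between cultures. In them 55% of 100 changes of log2 size 1 and 93% of 100 changes of log2 size 2 were recovered at 24h against 0h, with 5 false calls. They do not measure recovery by the model of time alone where cultures differ.

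The culture names recur at every time in titles and instrument records, so they pair the samples across times, and each count is also given with culture as a block. This was decided before the calls were compared. As a check, deviations from the time mean were correlated across probe sets between arrays of different times, where probe sets are not independent replicates. The median correlation was 0.44, 0.232 and 0.088 on the 3 chips for arrays of the same culture, against −0.199, −0.085 and −0.036 for arrays of different cultures, and not every same-culture pair exceeded 0.1.

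A total of 26 gene lists for muscle, cell cycle, signalling, stress and other cell types were fixed before the data were examined, as were the comparisons, thresholds, alternatives and the rule for naming genes. Lists were tested at 9 times with camera, using 1 probe set per gene and a preset correlation of 0.01, and again with an estimated correlation. The p values were adjusted over the 234 tests. Of these, 111 passed with the preset correlation and 40 with the estimated correlation, and all 40 were among the 111. Counts of list members are given after adjustment over all probe sets and also adjusted over the list alone.

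The rule named a fixed set of myogenic, muscle and cell division genes in every comparison. It added the 10 highest and 10 lowest genes at 24h and 7d, and the 3 highest and 3 lowest at other times, among those that passed and moved the same way in all 3 cultures. It also added up to 2 risen and 2 fallen members per list at the time with most calls, all passing members of the lists for other cell types at 7d, and the 10 genes with the smallest p in the culture and interaction tests, each by its probe set with the smallest p. *Pax7* and *Ccnb1* had no tested probe set with a single symbol. Other probe sets of named genes were compared in 193 gene, time and probe set combinations. In 34 of these both probe sets passed with the same sign, and in 106 neither passed, with signs that differed in 27 of them. In 45 only 1 passed and the signs were alike, in 8 only 1 passed and the signs differed, and in 0 did both pass in opposite directions.

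Alternatives covered normalization between arrays, the pseudocount, the filter, the variance prior, blocks for culture and scan session, adjustment within each chip, a 2-fold threshold, the arrays in the model, other phases, and leaving out each culture in turn. Fits against 0h with a culture left out had no block for culture. A call that ended without a culture therefore does not show that this culture carried the change. A further 4 alternatives left out arrays that stood apart and were chosen after seeing the data. Scan sessions came from instrument records, whose descriptions matched the culture and time of the label in 84 of 84 arrays that had one. The other 6 arrays had no scan date. A second scanner type read 6 arrays, which were those of 1999 at 4d and 7d on each chip. Sessions were mostly nested in cultures, and on MG_U74Av2 and MG_U74Bv2 no session held both 0h and 7d. The labels print the same RNA concentration for 6h and 12h within each culture, while 0 pairs of arrays were identical. The tools were R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Chip annotation was used for gene names and no positions in a genome are given.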

Results

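Gene expression was followed over 10 time points while primary myoblasts of MyoD-/- mice were moved from growth medium to a low-serum medium in which myoblasts form multinucleated myotubes. MyoD is a transcription factor that directs skeletal muscle differentiation. Each time point held 3 samples, 1 from each of the cultures 1999, P6 and P10, and each RNA sample was read on 3 chip designs, which gave 90 arrays. Signals of 24307 probe sets for 12373 genes were compared with those of growing cells at 0h. All samples were MyoD-/-, so the changes below are changes over time and not effects of the genotype. Folds were taken after a fixed value, the 25th percentile of the chip (119.8, 270.1 and 213.0), was added to each signal. Where the lower mean lay under that value, the fold is limited by background and is smaller than the ratio of the means, as is said beside it.

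The *Myod1* probe set gave signals between 2598 and 6889 in the 30 arrays, with a mean of 3733 ± 693 (SD, n = 3) at 0h. Its log2 fold changes against 0h lay between −0.20 and 0.35 and none passed the test. Which part of the transcript is deleted and which part the probe set covers were not analysed here, so this signal does not check the genotype. The related factor *Myf5* gave 2271 ± 325 at 0h and log2 fold changes between 0.03 and 0.99, none of which passed.

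The first comparison, 6h against 0h, asked which transcripts moved soon after the medium change. *Itm2a*, which encodes an integral membrane protein, rose 5.99-fold from 886 ± 273 to 6130 ± 2847 (SD, n = 3; log2 fold change 2.58 ± 0.36, adjusted p = 0.0031). *Ccng2*, a cyclin linked to cell cycle arrest, and *Acnat2*, an acyltransferase, each rose 3.27-fold. *Ccn2*, a matricellular protein, fell with a log2 fold change of −2.34 ± 0.46, *Cit*, a kinase of cytokinesis, with −1.89 ± 0.36, and *Mybl2*, a transcription factor of dividing cells, with −1.78 ± 0.29. A further *Mybl2* probe set gave 0.08 and a further *Cit* probe set −0.46, and neither passed.

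Of the gene lists at 6h, the one for S phase and DNA replication fell (camera adjusted p = 4.6e-16, and adjusted p = 0.0065 with an estimated correlation), with 2 of 33 members lower and 13 when adjusted over the list alone. The list for cell cycle exit rose (adjusted p = 5.9e-07, and adjusted p = 0.0076 with an estimated correlation), with 1 of 13 members higher and 5 adjusted over the list alone. Genes of G2 and M phase fell as a list (adjusted p = 7.4e-14), but with adjusted p = 0.070 with an estimated correlation and 0 of 41 members passing in limma, 15 at an unadjusted p under 0.05. The stress list for unfolded proteins and amino acid lack did not pass (adjusted p = 0.90). Its mean log2 fold change was 1.01 in P6 against −0.31 in 1999 and −0.39 in P10, and −0.35 over the other cultures when P6 was left out, and then the list passed as lower (adjusted p = 0.034). It also passed as lower without the P6 arrays of 6h and 12h (mean −0.38, adjusted p = 0.019), and its adjusted p lay between 0.019 and 0.98 over all alternatives. In all, 41 probe sets were differentially regulated at 6h, 24 upregulated and 17 downregulated. The count was 268 with culture as a block, 367 with scan session as a block, 0 with the 6 samples alone, and 7, 22 and 0 without 1999, P6 and P10. It was 87 without the P6 arrays of 6h and 12h, and 0 of the 6 calls on named genes held whichever culture was left out.

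At 12h against 0h, transcripts of cell division were lower. *Mki67*, which encodes a chromosome coat protein of dividing cells, fell 3.25-fold from 2056 ± 1000 to 513 ± 97 (log2 fold change −1.70 ± 0.25, adjusted p = 0.0009), while a second probe set of the gene gave 0.15 ± 0.23 and did not pass. *Pclaf*, a partner of the replication clamp, fell 5.42-fold, *Nmral1* 6.00-fold and *Fancb*, a DNA repair gene, 5.13-fold. *Itm2a* rose 7.97-fold, *Abca7*, a lipid transporter, 7.03-fold and *St3gal5*, a ganglioside synthase, 6.17-fold. Genes of G2 and M phase fell in 23 of 41 cases (33 adjusted over the list alone; camera adjusted p = 2.5e-40, and adjusted p = 0.0016 with an estimated correlation). Genes of S phase fell in 12 of 33 cases (27 adjusted over the list alone; adjusted p = 1.7e-25, and adjusted p = 0.00065 with an estimated correlation). A total of 300 probe sets were differentially regulated, 114 up and 186 down. The count was 848 with culture as a block (423 up and 425 down), 922 with scan session as a block, 0 with the 6 samples alone, and 48, 87 and 5 without 1999, P6 and P10. Of the 7 calls on named genes, 0 held whichever culture was left out.

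At 18h against 0h, most cell division genes were lower. Of the 41 genes of G2 and M phase 37 were lower, with a list mean of −2.44 (camera adjusted p = 9.9e-68, and adjusted p = 0.00024 with an estimated correlation), and 26 of 33 genes of S phase were lower. *Mki67* fell from 2056 ± 1000 to 31 ± 4 (log2 fold change −3.76 ± 0.25, adjusted p = 2.7e-09; second probe set 0.13 ± 0.23), *Anln*, a scaffold of the cleavage furrow, changed by −3.99 ± 0.50, and *Pclaf* by −3.83 ± 0.38. *Ogn*, a small proteoglycan of the matrix, rose 20.0-fold to 12421 ± 7575, *Itm2a* 16.9-fold and *Trdn*, a protein of the calcium release complex of muscle, 15.3-fold. Lower means under the added value limit the changes given for *Mki67* and *Trdn*, here and at each later time. Fibroblast markers rose as a list (adjusted p = 0.0040, and adjusted p = 0.033 with an estimated correlation), with 3 of 9 members higher. Cell cycle exit genes were higher in 3 of 13 cases, 7 adjusted over the list alone. Genes of muscle fusion and adhesion were higher in 4 of 18 cases and those of the neuromuscular synapse in 3 of 14, with adjusted p = 0.13 and adjusted p = 0.29 with an estimated correlation. Sarcomere genes passed in 1 of 38 cases, 13 with culture as a block, with list means of 3.18 in P10, 1.80 in P6 and 0.29 in 1999. A total of 1111 probe sets were differentially regulated, 436 up and 675 down. The count was 2123 with culture as a block (1047 up and 1076 down), 2201 with scan session as a block, 660 with the 6 samples alone, and 658, 273 and 438 without 1999, P6 and P10. The calls on *Ogn* and *Trdn* ended without P6, and those on *Anln*, *Itm2a*, *Mki67* and *Pclaf* held whichever culture was left out.

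**Figure D1:**
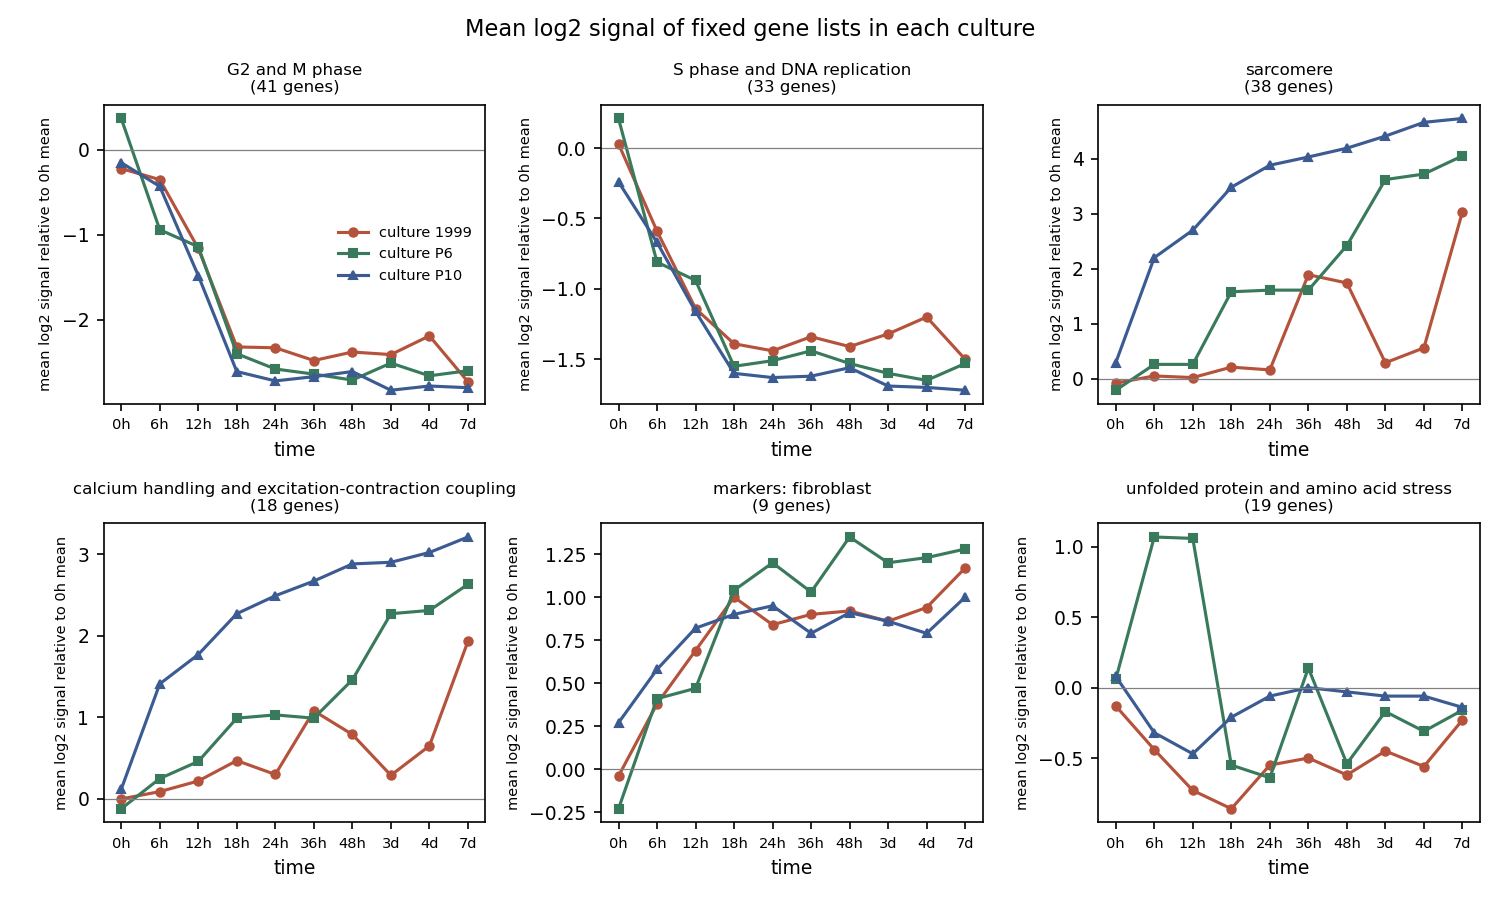
Mean log2 signal of 6 fixed gene lists, relative to the mean of the 0h samples (vertical axis), against time (horizontal axis, equally spaced), with 1 line and 1 marker shape per culture. At 18h the mean change from own 0h was −2.46 in P10, −2.77 in P6 and −2.10 in 1999 for genes of G2 and M phase, and 3.18, 1.80 and 0.29 in that order for sarcomere genes.

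At 24h against 0h, the genes named here were the highest and lowest of those that passed and moved the same way in all 3 cultures. *Anln* fell 20.0-fold from 7142 ± 1894 to 263 ± 187 (log2 fold change −4.32 ± 0.50, adjusted p = 7e-06), *Pbk*, a mitotic kinase, 18.2-fold, *Pclaf* 16.2-fold, *Mki67* 14.9-fold and *Top2a*, a topoisomerase of dividing cells, 14.1-fold. *Mki67*, *Top2a* and *Cenph* had 24h means of 18, 74 and 186, under the added value, which limits their folds. *Kif23*, *Aurka*, *Cenph*, *Ccnb2* and *Ndc80*, genes of spindle, kinetochore and mitotic entry, changed by log2 values between −3.54 and −3.37. For *Anln*, *Cenph*, *Kif23* and *Mki67*, 1 further probe set each gave a log2 fold change between −1.18 and −0.03 and did not pass. *Ogn* rose 21.1-fold to 12979 ± 7197 (log2 fold change 4.40 ± 0.81, adjusted p = 0.0015), *Itm2a* 19.8-fold, *Trdn* 15.3-fold, the basement membrane gene *Nid2* 11.7-fold and *Igfbp3*, a binding protein of insulin-like growth factors, 10.1-fold. *Aldh1a1*, a retinal dehydrogenase, rose 9.81-fold, the immediate-early gene *Fos* 8.43-fold, *St3gal5* 8.33-fold, *Abca7* 8.07-fold and *Chrng*, the fetal subunit of the acetylcholine receptor, 8.06-fold.

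Muscle lists at 24h had few passing members. Sarcomere genes passed in 0 of 38 cases in limma, 6 at an unadjusted p under 0.05 and 11 with culture as a block, with list means of 3.59 in P10, 1.82 in P6 and 0.24 in 1999, and the list call (camera adjusted p = 1.4e-05) was lost, with adjusted p = 0.52 with an estimated correlation. *Myog*, a late-acting myogenic factor, gave 13768 ± 17106 against 1664 ± 990 at 0h and *Acta1*, skeletal actin, 50633 ± 60144 against 1480 ± 1828, and neither passed (adjusted p = 0.62 and 0.37), though *Acta1* did with culture as a block (adjusted p = 0.017). Fibroblast markers rose in 3 of 9 cases (4 adjusted over the list alone; adjusted p = 0.031 with an estimated correlation) and the insulin-like growth factor list in 1 of 11 (adjusted p = 0.033 with an estimated correlation). A total of 1026 probe sets were differentially regulated, 455 up and 571 down. The count was 2018 with culture as a block (1080 up and 938 down), 2088 with scan session as a block, 586 with the 6 samples alone, and 646, 263 and 421 without 1999, P6 and P10. Of the 20 calls on named genes 12 held whichever culture was left out, and those on *Aldh1a1*, *Chrng*, *Fos*, *Igfbp3*, *Nid2*, *Ogn*, *St3gal5* and *Trdn* did not.

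At 36h against 0h, cell division lists were low, with 40 of 41 genes of G2 and M phase and 25 of 33 of S phase passing. *Kif23* fell 19.1-fold, *Pbk* 16.9-fold, *Anln* 16.7-fold and *Mki67* 15.0-fold. *Itm2a* rose 18.9-fold to 18362 ± 1047, *Ogn* 16.8-fold and *Trdn* 15.7-fold. The list for muscle fusion and adhesion rose (camera adjusted p = 4.5e-06, but adjusted p = 0.13 with an estimated correlation) with 5 of 18 members higher. Sarcomere genes passed in 0 of 38 cases in limma, 15 at an unadjusted p under 0.05 and 19 with culture as a block, with list means of 3.73 in P10, 1.82 in P6 and 1.97 in 1999. A total of 996 probe sets were differentially regulated, 439 up and 557 down. The count was 1914 with culture as a block (1042 up and 872 down), 1985 with scan session as a block, 525 with the 6 samples alone, and 461, 291 and 320 without 1999, P6 and P10. It was 652 without the 1999 arrays of 36h and 48h, and the calls on *Ogn* and *Trdn* ended without P6.

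At 48h against 0h, *Itm2a* rose 26.4-fold to 25758 ± 2078, *Trdn* 23.1-fold, *Aldh1a1* 21.8-fold and *Ogn* 21.6-fold, and the proteoglycan *Dcn* rose 3.09-fold. Fibroblast markers were higher in 4 of 9 cases (5 adjusted over the list alone; camera adjusted p = 0.0025, and adjusted p = 0.028 with an estimated correlation). *Cdkn1a*, which encodes the cyclin-dependent kinase inhibitor p21, rose 3.12-fold from 8286 ± 644 to 28577 ± 13775 (adjusted p = 0.043), and cell cycle exit genes were higher in 5 of 13 cases (7 adjusted over the list alone; adjusted p = 0.025 with an estimated correlation). In the interferon list *Ifi27* rose 2.59-fold and *Oasl2* fell 2.21-fold, to a mean of 168 under the added value. In the stress list the chaperone partner *Dnajb9* rose 2.58-fold, while *Vegfa*, an angiogenic factor, fell 3.58-fold and *Shmt2*, an enzyme of mitochondrial folate metabolism, 1.78-fold. Neither list passed (adjusted p = 0.21 and 0.15). *Anln* fell 19.8-fold, *Kif23* 17.4-fold, *Pclaf* 16.0-fold and *Mki67* 14.4-fold. A total of 1416 probe sets were differentially regulated, 584 up and 832 down. The count was 2689 with culture as a block (1351 up and 1338 down), 2727 with scan session as a block, 663 with the 6 samples alone, and 756, 338 and 695 without 1999, P6 and P10. Of the 15 calls on named genes, those on *Anln*, *Ifi27*, *Itm2a*, *Kif23*, *Mki67* and *Pclaf* held whichever culture was left out.

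At 3d against 0h, *Itm2a* rose 27.0-fold, *Trdn* 18.9-fold and *Pygm*, muscle glycogen phosphorylase, 16.1-fold from 148 ± 84 to 6131 ± 6206 (log2 fold change 4.01 ± 1.04, adjusted p = 0.024). *Anln* fell 19.3-fold, *Kif23* 16.9-fold and *Mki67* 14.3-fold. The list of myogenic transcription factors rose (camera adjusted p = 0.0012, and adjusted p = 0.033 with an estimated correlation) with 0 of 14 members passing alone in limma, 5 at an unadjusted p under 0.05 and 6 with culture as a block. Among them *Mef2c* gave 3798 ± 3583 against 44 ± 22 and *Myog* 17182 ± 14102 against 1664 ± 990 (adjusted p = 0.15 and 0.46, and 0.0025 and 0.025 with culture as a block). Calcium handling genes were higher in 3 of 18 cases (5 adjusted over the list alone), with adjusted p = 0.34 with an estimated correlation. A total of 1156 probe sets were differentially regulated, 488 up and 668 down. The count was 2424 with culture as a block (1272 up and 1152 down), 2031 with scan session as a block, 427 with the 6 samples alone, and 905, 372 and 390 without 1999, P6 and P10. The calls on *Pygm* and *Trdn* ended without P6.

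At 4d against 0h, *Trdn* rose 23.3-fold, *Itm2a* 22.6-fold and *Aldh1a1* 18.7-fold, and *Cdkn1a* rose 3.36-fold (adjusted p = 0.031). *Pbk* fell 19.7-fold, *Anln* 17.0-fold, *Cdk1*, the kinase of mitotic entry, 16.6-fold and *Mki67* 11.9-fold. Sarcomere genes passed in 0 of 38 cases in limma, 15 adjusted over the list alone, 29 at an unadjusted p under 0.05 and 32 with culture as a block, with a list mean of 0.64 in 1999 against 3.94 in P6 and 4.37 in P10. Genes of cholesterol synthesis rose as a list (camera adjusted p = 3.4e-06, but adjusted p = 0.34 with an estimated correlation) with 0 of 19 members passing in limma, 11 at an unadjusted p under 0.05 and 10 with culture as a block. A total of 1357 probe sets were differentially regulated, 597 up and 760 down. The count was 2683 with culture as a block (1419 up and 1264 down), 1546 with scan session as a block, 536 with the 6 samples alone, and 984, 343 and 425 without 1999, P6 and P10. The calls on *Aldh1a1*, *Cdk1*, *Cdkn1a* and *Trdn* ended without P6, and those on *Anln*, *Itm2a*, *Mki67* and *Pbk* held whichever culture was left out.

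**Figure D2:**
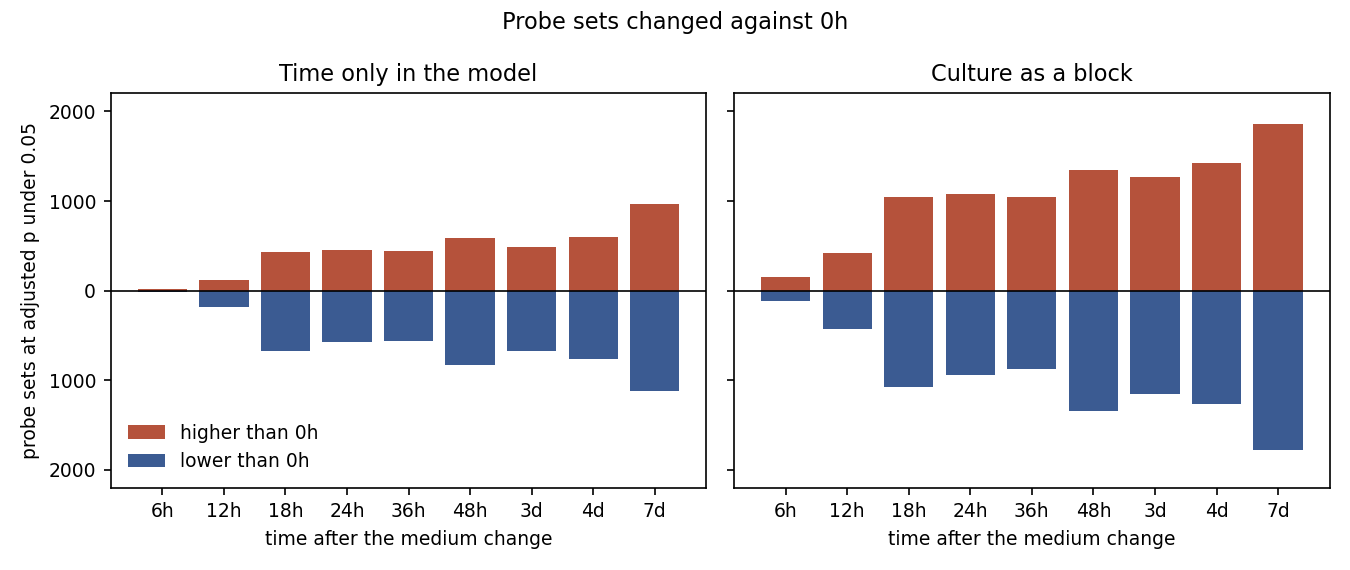
Probe sets at adjusted p under 0.05 against 0h (vertical axis, higher above the line and lower below it) at each later time (horizontal axis), for a model of time alone and for one with culture as a block. Counts lay between 41 at 6h and 2092 at 7d in the first panel and between 268 and 3633 in the second.

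At 7d against 0h, the 10 highest of the genes that passed and moved the same way in all 3 cultures were 7 named here and *Mb*, *Atp2a1* and *Trdn*, given with their lists below. The embryonic myosin light chain gene *Myl4* rose 192-fold from 539 ± 621 to 95905 ± 39483 (SD, n = 3; log2 fold change 7.59 ± 2.05, adjusted p = 0.020). Slow troponin C (*Tnnc1*) rose 173-fold, the fast myosin heavy chain *Myh1* 136-fold, the fast light chain *Myl1* 134-fold, the costamere gene *Smpx* 110-fold, fast troponin T (*Tnnt3*) 55.6-fold and *Mybph*, a myosin-binding protein, 50.5-fold. *Myh1* and *Smpx* had 0h means of 82 and 239, under the added value, which limits their folds. A second *Myl4* probe set gave a log2 fold change of 0.80 and did not pass. Sarcomere genes were higher in 16 of 38 cases, 34 adjusted over the list alone and 35 with culture as a block (camera adjusted p = 6.3e-16, but adjusted p = 0.22 with an estimated correlation). *Acta1* gave 106350 ± 45949 against 1480 ± 1828 (adjusted p = 0.051) and the embryonic heavy chain *Myh3* 21347 ± 17036 against 92 ± 115 (adjusted p = 0.096), and both passed with culture as a block (adjusted p = 0.00015 and 0.00024). *Ckm*, muscle creatine kinase, gave 797 ± 327 against 1022 ± 290 (log2 fold change −0.36, adjusted p = 0.57), while further probe sets of the gene gave log2 fold changes of 2.07 ± 1.07, 2.28 ± 1.06 and 0.03 ± 0.30, none of which passed.

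Other muscle lists held passing members at 7d. Calcium handling genes were higher in 6 of 18 cases (14 adjusted over the list alone), among them the calcium pump *Atp2a1*, 52.5-fold, and *Trdn*, 44.9-fold (adjusted p = 0.22 with an estimated correlation). Genes of the neuromuscular synapse were higher in 6 of 14 cases (10 adjusted over the list alone), with the acetylcholine receptor subunits *Chrng* at 13.5-fold and *Chrna1* at 13.4-fold (adjusted p = 0.15 with an estimated correlation). Fusion and adhesion genes were higher in 10 of 18 cases (12 adjusted over the list alone), with the fusion factor *Mymk* at 43.7-fold, reaching 100456 ± 34250, and the caveolar gene *Cav3* at 22.1-fold (adjusted p = 0.091 with an estimated correlation). Genes of muscle energy metabolism were higher in 4 of 19 cases (9 adjusted over the list alone), with myoglobin (*Mb*) at 55.9-fold and *Cox6a2*, a muscle subunit of cytochrome oxidase, at 30.7-fold (adjusted p = 0.38 with an estimated correlation), from 0h means of 113 and 90 that lay under the added value and limit these folds. Of the 14 myogenic transcription factors 1 passed, and 5 with culture as a block. It was *Mef2c*, at 32.4-fold from 44 ± 22 to 6294 ± 4466 (adjusted p = 0.025), a fold limited by the added value, while 5 further *Mef2c* probe sets were higher without passing. *Myog* gave 17968 ± 5716 against 1664 ± 990 (adjusted p = 0.20) and *Myf6* 2422 ± 2796 against 302 ± 234 (adjusted p = 0.091), and both passed with culture as a block (adjusted p = 0.0016 and 0.00095). The list of myogenic factors had adjusted p = 0.14 with an estimated correlation.

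Cell division genes were lower at 7d, with list means for G2 and M phase of −2.52 in 1999, −2.96 in P6 and −2.65 in P10. All 41 genes of that list passed (adjusted p = 0.00038 with an estimated correlation), among them *Cdk1*, 18.4-fold, and *Mki67*, 15.4-fold. Of 33 genes of S phase 26 were lower (27 adjusted over the list alone; adjusted p = 0.0012 with an estimated correlation), among them *Uhrf1*, which maintains DNA methylation, 9.93-fold, and the helicase subunit *Mcm5*, 9.04-fold, whose second probe set gave a log2 fold change of 0.17. Beyond the lists, *Anln* fell 27.9-fold, *Kif23* 22.8-fold, *Hmga2*, a chromatin protein of growing cells, 20.5-fold from 22644 ± 2986 to 1298 ± 1234, *Pclaf* 17.4-fold, *Serpinb2*, an inhibitor of plasminogen activators, 17.3-fold, *Top2a* 14.9-fold, *Mthfd1l*, a folate enzyme, 13.0-fold and *Pbk* 12.9-fold. For *Mki67*, *Kif23* and *Top2a*, 7d means of 13, 115 and 59 under the added value limit the folds. Cell cycle exit genes were higher in 5 of 13 cases (8 adjusted over the list alone; adjusted p = 0.028 with an estimated correlation), with *Gas6* at 4.34-fold and *Cdkn1a* at 3.82-fold. Ribosomal protein genes fell in 7 of 14 cases (11 adjusted over the list alone), with *Rpl13a* at 2.51-fold and *Rps3* at 1.86-fold lower, and adjusted p = 0.14 with an estimated correlation.

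Signalling and matrix genes moved both ways at 7d. In the immediate-early and growth factor list *Fos* rose 15.7-fold and *Spry1* 3.37-fold while *Dusp5* fell 6.78-fold and *Plaur* 6.02-fold, with 2 of 27 members higher and 6 lower (adjusted p = 0.23). In the list for Id genes and BMP and TGF-beta responses *Fst*, an antagonist of activin and myostatin, rose 17.9-fold and *Bmp4* 3.01-fold while *Id2* fell 4.19-fold and *Smad7* 3.63-fold, with 3 of 14 members moving each way (adjusted p = 0.77), a mean of 0.07 and a median of −0.44. A second *Bmp4* probe set gave a log2 fold change of −0.96 and did not pass. The insulin-like growth factor list rose (adjusted p = 0.046 with an estimated correlation) with 2 of 11 members higher, *Igfbp3* at 4.57-fold and *Igf2r* at 1.97-fold. *Igf1* did not pass by the probe set chosen for it (log2 fold change 0.30), whereas 3 further probe sets rose by log2 values between 1.84 and 2.94. Collagen and matrix genes were higher in 7 of 30 cases and lower in 1 (adjusted p = 0.23 with an estimated correlation), with *Postn* at 20.7-fold and *Col6a1* at 5.00-fold higher and the protease inhibitor *Timp1* at 3.95-fold lower.

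Markers of other cell types were checked beside these changes. Fibroblast markers were higher in 3 of 9 cases at 7d (adjusted p = 0.028 with an estimated correlation), namely *Ogn* 21.5-fold, *Dcn* 8.58-fold and the transcription factor gene *Tcf4* 2.15-fold. *Tcf4* encodes an E protein and is a different gene from *Tcf7l2*, whose product is the fibroblast marker also called TCF4. It counts among the 9 at every time, because the list was fixed with it. *Ogn* and *Dcn* are also matrix genes that muscle cultures express. Smooth muscle markers were higher in 3 of 11 cases and lower in 1, with *Synpo2* at 6.12-fold, *Acta2* at 4.96-fold and *Mylk* at 2.18-fold higher and *Tpm4* at 2.85-fold lower (adjusted p = 0.18 with an estimated correlation). Of the Schwann cell and neural crest markers *Pmp22* was 2.76-fold higher, 1 of 6. Further probe sets of *Synpo2* and *Pmp22* gave log2 fold changes of −0.45 and −0.36. With limma 0 members passed among 4 adipocyte, 2 cartilage and bone, 4 endothelial and 6 macrophage and leukocyte markers, and none of these lists passed. Of these markers 2 endothelial and 1 leukocyte had an unadjusted p under 0.05, and 1 endothelial and 3 leukocyte passed with culture as a block. Between cultures, 2 adipocyte, 1 cartilage and bone, 0 endothelial and 3 macrophage and leukocyte markers differed, where 24.0% of all probe sets did. In the late minus early change 2 macrophage and leukocyte markers differed between cultures and 0 of the adipocyte, cartilage and bone, and endothelial markers, where 1.8% of all probe sets did. The mean of the 4 adipocyte markers, relative to the 0h mean of all cultures, went from −0.23 at 0h to 1.45 at 7d in 1999. At 7d it was −0.02 in P6 and −0.43 in P10. These values come from 1 sample each and were chosen after they were seen. The 7d arrays of 1999 were read on the second scanner type.

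Other probe sets of named genes did not always pass with the chosen one. A second probe set of *Mki67* from 12h on, and 1 of 2 others of *Kif23* at 24h, 36h, 48h, 3d and 7d, stayed between log2 fold changes of −0.37 and 0.15, and 1 of *Anln* reached −1.18 at 24h without passing up to 4d. At 7d further probe sets of *Fst* (1.15), *Uhrf1* (−0.78), *Acta2* (0.51), *Tcf4* (0.78), *Rps3* (−0.22 and −0.54) and *Mylk* (0.58 and 0.97) moved the same way without passing, as did those of *Vegfa* at 48h (−0.92) and *Chrng* at 24h (2.50). A second *Cdkn1a* probe set passed at 18h, 24h, 36h and 3d where the chosen one did so only with culture as a block (log2 fold changes of the second between 1.54 and 1.61), and a further *Igf1* probe set rose by between 2.05 and 2.87 from 48h to 7d.

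Over all probe sets, 2092 were differentially regulated at 7d against 0h, 970 up and 1122 down, a balance that turned with median centring (1046 up and 999 down) and with culture as a block (1856 up and 1777 down). The count was 3633 with culture as a block, 2194 with scan session as a block, 1834 with the 6 samples alone, and 1628, 654 and 877 without 1999, P6 and P10. Of the 53 calls on named genes 18 held whichever culture was left out, and 32 ended without P6, 15 without P10 and 8 without 1999. These fits had no block for culture, so differences between the cultures left counted as spread. Without P6 the cultures left were 1999 and P10, the pair with most probe sets that differed. The calls on *Myl4*, *Tnnc1*, *Myh1*, *Myl1*, *Smpx*, *Tnnt3* and *Mybph* all ended without at least 1 culture, as did those on *Mb*, *Cox6a2*, *Atp2a1*, *Mymk*, *Cav3*, *Mef2c*, *Chrna1* and *Chrng*, while that on *Trdn* held.

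**Figure D3:**
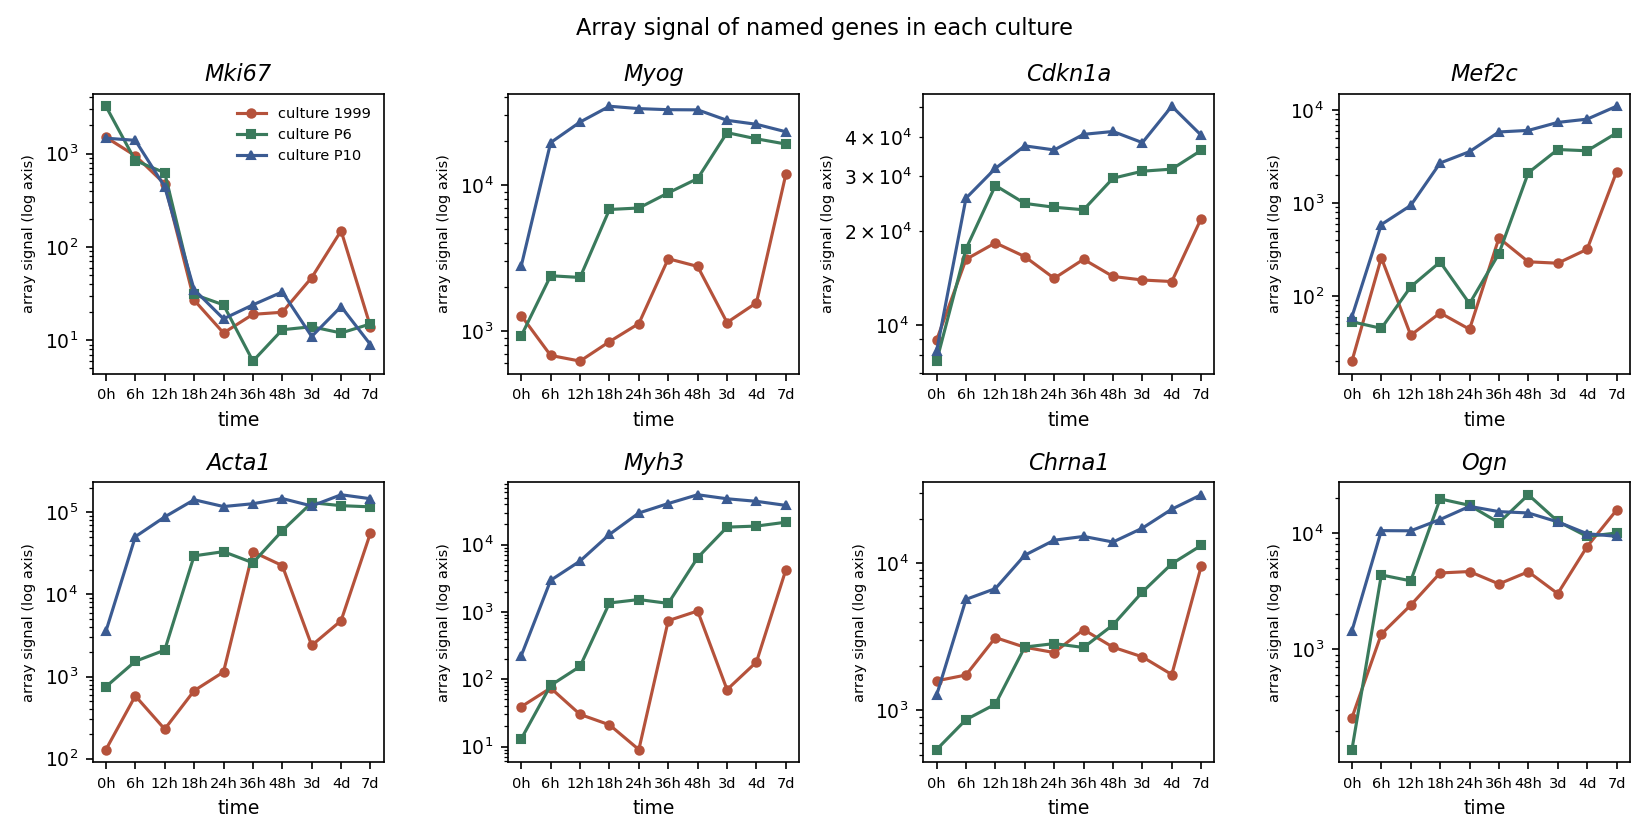
Array signal (vertical axis, log scale) of 8 named genes against time (horizontal axis, equally spaced), 1 sample per point and 1 line per culture. *Mki67* was between 27 and 35 in all cultures at 18h, while *Myog* at that time was 34497 in P10, 6785 in P6 and 846 in 1999.

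Neighbouring times from 6h on were compared to find when changes took place. The step from 0h to 6h, given above, had 41 passing probe sets (268 with culture as a block) and is not counted here. Between 12h and 18h 19 probe sets fell and 0 rose. They included *Anln* (log2 fold change −2.82 ± 0.50), *Birc5*, an inhibitor of apoptosis that acts in mitosis (−2.27 ± 0.25), *Plk1* (−2.18 ± 0.36), *Mki67* (−2.06 ± 0.25), *Cdc20* (−1.74 ± 0.30) and *Bub1* (−1.69 ± 0.26), all genes of mitosis. *Ogdh*, a subunit of a citric acid cycle enzyme, fell by 1.51 ± 0.26 from 12h to 18h and was 1.61 ± 0.26 higher at 24h than at 18h, the only probe set to pass in that comparison. *Ogdh* and the mitotic genes other than *Mki67* were chosen here after their values were seen. The other 6 comparisons of neighbouring times gave 0 passing probe sets by limma, with 473 to 789 at an unadjusted p under 0.05 and also 0 with culture as a block. The total of 20 was 32 with culture as a block, 36 with scan session as a block, 0 with the 6 samples of each comparison alone, and 1, 6 and 0 without 1999, P6 and P10. The joint test over all times passed for 795 probe sets, for 2020 with culture as a block and 1272 with scan session as a block, and for 349, 136 and 185 without 1999, P6 and P10.

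The cultures also differed from each other in a model with time and culture, while no difference was tested at a single time. The 10 times of a culture counted as its samples there, so the p values do not measure the spread between independent cultures. *Col1a2*, a chain of type I collagen, gave 54183 ± 7193 (mean ± SD over 10 times) in 1999 against 101 ± 35 in P6 and 241 ± 182 in P10 (limma adjusted p = 2e-18), although a second probe set of the gene gave 5043, 5085 and 5241. *Cd99* gave 16601 in 1999 against 521 and 565, the endodermal factor *Foxa2* 1804 against 138 and 120, the positional gene *Hoxa3* 1966 against 101 and 66, *Cyba*, a subunit of NADPH oxidase, 5557 against 1027 and 968, and *Pdk4*, a kinase of pyruvate dehydrogenase, 8350 against 1195 and 753. In the other direction *Zic1* gave 21 in 1999 against 1735 and 1369, *Sim2* 23 against 847 and 752, and *Hoxa11* 78 against 1421 and 1290. Second probe sets gave 1055 in 1999 against 366 and 274 for *Hoxa3*, 1802 against 145 and 157 for *Cyba*, 172 against 882 and 949 for *Zic1*, and 999 against 2014 and 1513 for *Sim2*, which did not pass (adjusted p = 0.056). The Y-linked gene *Eif2s3y* gave 73 in 1999 against 752 and 1427. *Xist*, the RNA of the inactive X chromosome, gave 1515 (491 to 3075) in 1999 against 70 (16 to 265) and 44 (13 to 86), and was chosen after its values were seen.

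In all, 5831 probe sets, 24.0% of those tested, differed between cultures. Without 1999, P6 and P10 the count was 1683, 5799 and 1832, and 1337 differed by at least 2-fold. A total of 57 probe sets lay at least 4-fold from 1999 in both other cultures, 29 higher and 28 lower in 1999. Between pairs of cultures 64 probe sets passed with at least a 4-fold difference for P6 and 1999, 198 for P10 and 1999 and 45 for P10 and P6. Sarcomere genes differed between cultures in 34 of 38 cases. On MG_U74Av2 and MG_U74Bv2 no scan session held 1999 together with another culture. There, 50 probe sets at least 4-fold apart shifted between sessions within 1999 and P6 by a median log2 value of 0.39, against 2.80 between cultures. Shifts within a culture do not measure those between the sessions that part the cultures. On MG_U74Cv2 1 session held arrays of 1999 from 0h to 3d, of P6 at 3d, 4d and 7d and of P10 at 7d. At 3d in that session 7 of 7 probe sets at least 4-fold apart differed between 1999 and P6 in the same direction as over all times.

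**Figure D4:**
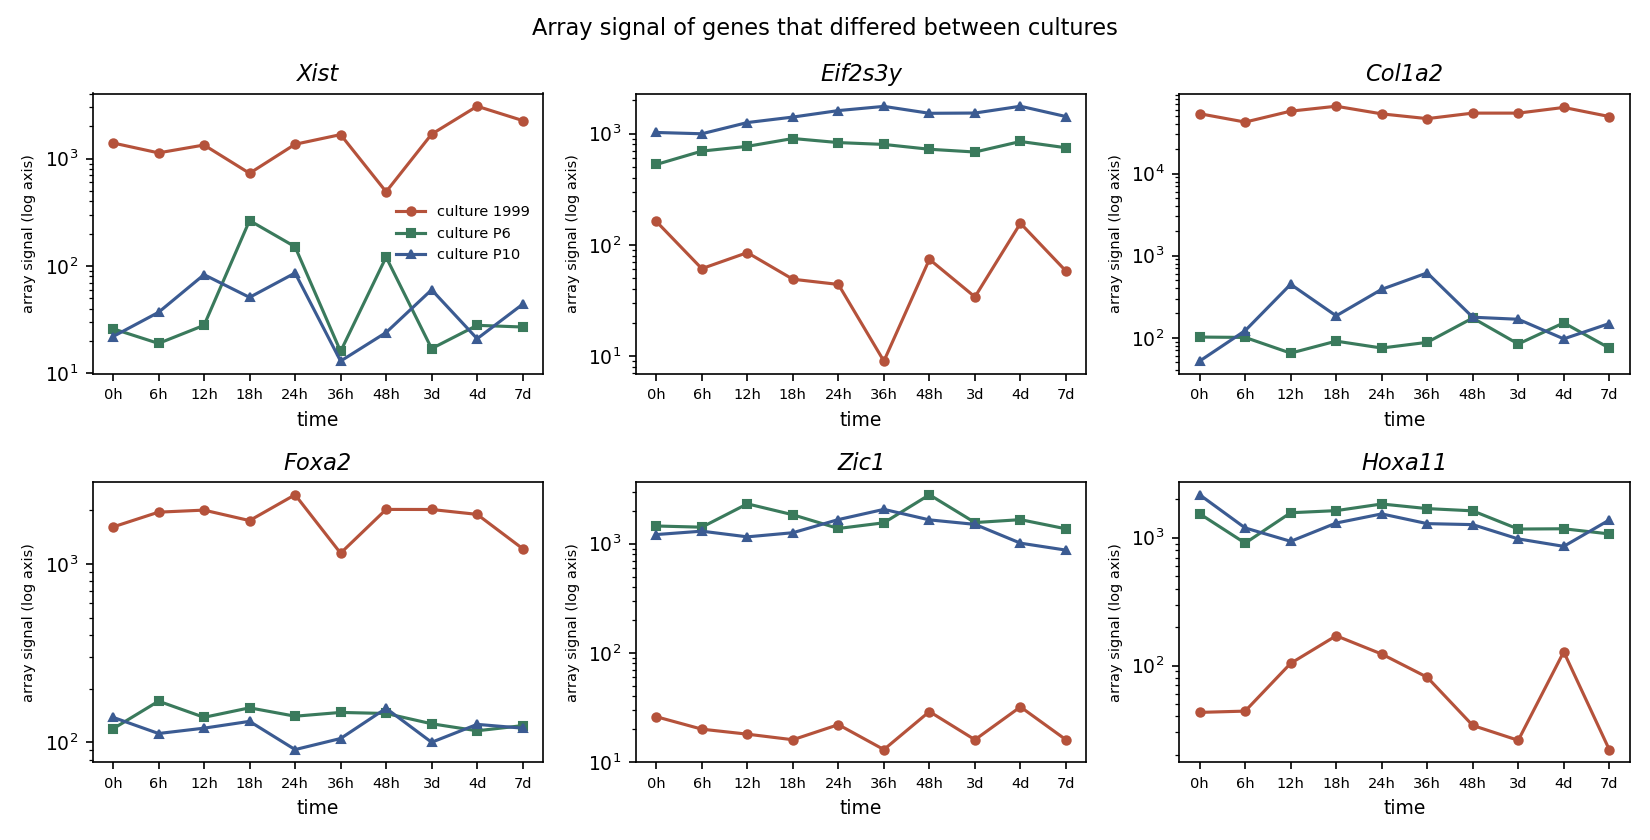
Array signal (vertical axis, log scale) of 6 genes against time (horizontal axis, equally spaced), 1 sample per point and 1 line per culture. *Xist*, *Col1a2* and *Foxa2* lay above the other cultures in 1999 at all 10 times, and *Eif2s3y*, *Zic1* and *Hoxa11* below them.

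The change from the early phase (0h, 6h and 12h) to the late phase (3d, 4d and 7d) was compared between cultures. The times of a phase counted as samples of a culture there, so the p values do not measure the spread between independent cultures. *Cd53*, a tetraspanin of leukocytes, had mean signals of 4928 early and 605 late in P6 and of 1072 and 12 in P10, against 27 and 14 in 1999 (adjusted p = 3e-04). *Cd24a*, a surface glycoprotein, went from 564 to 7074 in P10 and from 751 to 2068 in P6, and from 4650 to 2445 in 1999 (adjusted p = 0.0023). *Eps8*, an actin regulator, went from 1822 to 407 in P6 and from 1383 to 130 in P10, and from 565 to 908 in 1999, and the growth factor *Fgf7* from 1074 to 2616 in 1999 and from 2268 to 950 in P10. A total of 435 probe sets, 1.8%, passed. Of the 38 sarcomere genes 4 did, with late minus early list means of 1.30 in 1999, 3.69 in P6 and 2.87 in P10. Leaving out 1999 left 3 probe sets, leaving out P6 or P10 170 and 184, leaving out the 1999 arrays of 4d and 7d 131, leaving out the P6 arrays of 6h and 12h 146, and moving 18h to 48h into the phases 11. The 1999 arrays of 4d and 7d were those read on the second scanner type. On each chip, early and late arrays of P6 were read in different sessions.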

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

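Chosen only after the result was seen were all tests of explanations for the first 2 patterns below, the tests of mislabelled and of exchanged arrays, that of scan session on MG_U74Av2 and MG_U74Bv2, the comparison at 3d alone and the draws with culture means removed, while the other tests of the last pattern and the splits were written before. Of these tests 5 were also changed after a value had been seen. The test of exchanged labels first took any interval above 0 as fitting, before a bound was set from the fall of at least 0.5 required in P6 and P10. The test of mixed RNA ran in 3 versions, and the difference in cell division genes was first read with a margin of 0.5, which left it undecided. The test of myogenic cells first used 4 genes at 0h alone, with a median of −0.62. The test of mislabelled arrays ran in 3 versions, first on the order of *Xist* and *Eif2s3y*, which belong to the pattern (30 of 30 samples), then as a count of arrays nearest to their own culture (85 of 90), which left it undecided, and the test on arrays of 1999 alone was added after that count was known. Intervals in parentheses below run over resampled genes or probe sets, which are not replicates, or are binomial for shares of probe sets. They do not measure the spread between samples.

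The late minus early change differed between cultures for 435 probe sets, by an interaction test. Of 100 draws of culture labels within times, the real one included, 7 gave as many, with a highest count of 1267, so chance was not excluded by them. These draws also exchange the levels of the cultures, a structure of the samples. With the mean of each culture removed, 1 of 100 draws gave as many, the real one, and the highest other was 11. Each culture was a single series, and the draws exchange single times between series. They therefore do not measure the spread between independent cultures, and chance between cultures is not excluded. The smallest adjusted p values belonged to *Cd53* (3e-04), *Cd24a*, *Uhmk1* and *Eps8* (0.0023 each), *Tas1r1* and *Ctrb1* (0.0044 each), *Lhfp* (0.0067), *Jade2* (0.0072), and *Fgf7* and *Snx9* (0.0083 each). Log2 changes from early to late in 1999, P6 and P10 were 1.57, −0.40 and −0.59 for *Uhmk1*, −0.09, 1.92 and 2.50 for *Tas1r1*, and −0.69, 2.11 and 1.95 for *Ctrb1*. They were 0.77, −0.23 and −1.96 for *Lhfp*, 1.94, 0.06 and −0.21 for *Jade2*, and 0.94, −0.47 and −0.99 for *Snx9*. A second *Uhmk1* probe set went the other way in 1999, with −1.55, 0.15 and −0.31 (adjusted p = 0.028), and another gave 0.24, 0.11 and 0.24 (adjusted p = 0.97). A second *Snx9* probe set gave 0.47, 0.05 and −0.50 (adjusted p = 0.066).

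In culture 1999, sarcomere genes lay higher at 36h and 48h (list means 1.97 and 1.82) than at 3d and 4d (0.37 and 0.64), and the 48h sample had the highest 3' to 5' log2 ratios of control probe sets of all samples, −0.02 for *Gapdh* and 0.45 for actin. Scan session is argued against, since within 1 session the mean at 48h was 1.45 above that at 3d (1.14 to 1.81), with 36 of 38 genes higher, and that at 36h 1.60 above it. RNA of P10 mixed into the 36h and 48h samples is argued against by 12 genes that were lower in 1999 early, which rose by 0.8% of the P10 signal (−1.8 to 3.0) where sarcomere genes rose by 10.8% (8.9 to 13.6), although earlier versions with 3 genes (4.5%, 1.1 to 83.7) and 13 genes (13.7%, 6.0 to 42.5), set against 16.4% (12.4 to 19.8), were undecided. Exchanged time labels stay open, since 222 genes that fell in P6 and P10 between these times had a median change of 0.06 in 1999 (0.01 to 0.12) with 42.3% below 0, which lies between the bounds set for and against a swap. No biological explanation was tested, as the design names none.

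List means of sarcomere genes at 18h were 3.18 in P10, 1.80 in P6 and 0.29 in 1999, with 1 sample per culture and time and no test of timing. Scan session is argued against for P6 and 1999, since the sarcomere change to 24h was 1.58 larger in P6 than in 1999 (1.21 to 1.97) with each culture read within 1 session. For P10 it was not tested, and on MG_U74Av2 its 0h and 18h arrays were read in different sessions. A smaller share of myogenic cells in 1999 is argued against as the whole cause, since *Myf5*, *Itga7* and *Cdh15* over 0h, 6h and 12h had a median of −0.71 in 1999 minus P10 (range −1.46 to 0.79, 9 values), against −3.49 (−4.21 to −2.81) for sarcomere genes at 18h and 24h. This assumes that sarcomere signal follows the share of myogenic cells in proportion, which was not tested. *Itga7* and *Cdh15* were lower in 1999 at each of these times and *Myf5* higher, so a smaller share stays open as a part. A later loss of cell division genes in 1999 stays open, since genes of G2 and M phase fell by 0.36 less than in P10 by 18h (0.14 to 0.58 over genes). With 1 sample per culture and time, this difference has no measure of the spread between samples. In P6, however, genes of G2 and M phase fell further (−2.77) than in P10 (−2.46), from a higher level at 0h, while its sarcomere mean at 18h was lower. Relative to the 0h mean of all cultures, levels of these genes at 18h were −2.32 in 1999, −2.4 in P6 and −2.61 in P10. This order goes with a later loss but also with a smaller one. In 1999 the level stayed between −2.48 and −2.19 from 24h to 4d and was −2.73 at 7d, so it hardly fell further soon after 18h. Levels of S phase genes went from 0.03 at 0h to −1.39 at 18h in 1999 and from −0.24 to −1.6 in P10. These values do not tell a later loss from a smaller one. What the culture names stand for was not tested.

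Sex-linked and positional genes set 1999 apart from P6 and P10. Scan session is argued against for 7 probe sets on MG_U74Cv2, chosen over all arrays, these included. All 7 differed the same way between 1999 and P6 within 1 session, by a median of 2.73 (2.16 to 6.28) with mostly different times. The median was 2.90 at 3d, the only time both cultures share there. On MG_U74Av2 and MG_U74Bv2 scan session stays open, since no session there held 1999 together with another culture. On these chips 50 probe sets at least 4-fold apart, muscle genes among them, shifted between sessions within 1999 and P6 by a median of 0.39 (0.26 to 0.55), against 2.80 between cultures. The largest shift was 4.66, for *Myh3*, where sessions also differ in time. These probe sets were chosen for differing between cultures, and shifts within a culture do not measure those between the sessions that part the cultures. A sequence variant under single probe sets stays open for the set. Of 27 other probe sets 23, 85.2% (66.3 to 95.8), went the same way, of which 11 passed. Some of the 27, such as those of *Cyba*, *Meg3* and *Cox6b2*, were themselves chosen as at least 4-fold apart, so the share does not decide. Among named genes, second probe sets of *Hoxa3*, *Cyba* and *Zic1* passed the same way, which argues against a variant for these 3. That of *Sim2* went the same way without passing, and that of *Col1a2* gave 5043, 5085 and 5241. Arrays exchanged between 1999 and another culture are argued against. Over probe sets outside the pattern, 30 of 30 arrays of 1999 correlated best with 1999 (smallest margin 0.104). A wrong label on single arrays was not decided by leaving out the 5 P6 arrays nearest to another culture. Without them 93.8% (82.8 to 98.7) of 48 probe sets on MG_U74Av2 and MG_U74Cv2 stayed at least 4-fold apart. These were chosen as 4-fold apart over the same arrays, and few arrays were left out, so most were likely to stay so whatever the labels. A biological difference between the cultures stays open as a hypothesis and was not tested, since the labels do not say how they differ.

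Each comparison of 3 samples against 3 has 10 splits, too few for a share under 0.05. The real counts from 6h to 7d against 0h were 41, 300, 1111, 1026, 996, 1416, 1156, 1357 and 2092, and the highest of the other splits 2, 2, 0, 1, 2, 1, 0, 3 and 3. In each of these, 1 of 10 splits gave as many. Among the splits that part all 3 culture pairs, as the real one does, the highest others were 0, 0, 0, 1, 0, 1, 0, 0 and 3, while the remaining splits leave a culture undivided. Between 12h and 18h the real count was 19 and the highest other 0, and between 18h and 24h they were 1 and 1, with 2 splits that gave as many. In the other 6 neighbouring comparisons, where the real count by limma was 0 and 473 to 789 probe sets had an unadjusted p under 0.05, all 10 splits gave as many, with highest others of 1 to 3.

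For the tests over all samples 100 draws were used, the real grouping included. Only the real grouping gave as many calls for the joint test over time (795, highest other 375, 1 draw with as many). The same held for the difference between cultures (5831, highest other 23, 1 draw with as many). Each culture was 1 series of samples, read mostly in its own scan sessions. The draws therefore do not tell a difference between cultures from one between sessions, nor measure the spread between independent cultures. For the gene lists (111) 2 of 100 draws gave as many, a share under 0.05, though 1 other grouping gave more, 121.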

How the results depend on the processing

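The alternatives were written before the data were examined, except for 4 that left out arrays and were chosen after seeing the data. Quantile normalization and median centring kept all 14 counts within 1.5 times and moved the share of higher probe sets by at most 10 points. Of 259 counts 79 moved by more than that, of 4212 tests of gene lists 154 were lost, 99 were gained and 2 changed sign, of 4575 of named genes 223 were lost, 112 were gained and 8 changed sign, and of 327 of culture genes 29 were lost. The cause was not tested, apart from fewer samples where a culture, arrays or other times were left out and fewer tests under the stricter filter. With the pseudocount, signals under about 120 to 270 hardly move the log2 value, so fold changes of dim genes are limited by signal over background, and detection calls were not used here. A culture left out leaves 2 samples per time, whose spread is pooled over times. Without a block, that spread holds the differences between the cultures left. Between P10 and 1999, left without P6, 5896 probe sets differed, against 2404 between P6 and 1999 and 2019 between P10 and P6.

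With culture as a block, which pairs the samples, the counts from 6h to 7d were 268, 848, 2123, 2018, 1914, 2689, 2424, 2683 and 3633, the neighbouring times gave 32 and the joint test 2020. All probe sets called against 0h without the block were also called with it. With scan session as a block the counts were 367, 922, 2201, 2088, 1985, 2727 and 2031 from 6h to 3d, then 1546 and 2194, with 36 for neighbouring times and 1272 for the joint test. The culture and interaction tests could not be fitted with a session block, the culture block cannot be added to tests of culture, and the joint, culture and interaction tests have no version with the samples of 1 comparison. With those samples alone the counts from 6h to 4d were 0, 0, 660, 586, 525, 663, 427 and 536, at 7d 1834, and for neighbouring times 0.

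The interaction count of 435 was 254 with a pseudocount of 0, 771 with the chip median, 717 with the 75th percentile filter, 710 with a variance trend and 11 with other phases. Without the 1999 arrays of 4d and 7d, those read on the second scanner type, it was 131, and without the P6 arrays of 6h and 12h 146. The 6h count of 41 was 77 with the chip median, 75 with the 75th percentile filter, 73 with adjustment within each chip and 87 without the P6 arrays of 6h and 12h. The total of 20 for neighbouring times was 11 with that filter, the culture count 1337 with a 2-fold threshold, the 36h count 652 without the 1999 arrays of 36h and 48h, and the count of lists 40 with an estimated correlation. Leaving out the 1999 arrays of 48h moved none of the 14 counts by over 1.5 times, and the 48h count was 1052.

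Leaving out 1 culture in turn gave 0 to 22 probe sets at 6h, 5 to 87 at 12h, 273 to 658 at 18h, 263 to 646 at 24h, 291 to 461 at 36h, 338 to 756 at 48h, 372 to 905 at 3d, 343 to 984 at 4d and 654 to 1628 at 7d. It gave 0 to 6 for neighbouring times, 136 to 349 for the joint test, 1683 to 5799 for culture, 3 to 184 for the interaction and 104 to 120 for the lists.

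The stress list at 6h had a mean of 0.10, of −0.35 to 0.35 with 1 culture left out (−0.35 without P6) and of −0.38 without the P6 arrays of 6h and 12h, passing as lower in these 2 cases. Further probe sets turned the sign of *Mki67* (0.15 at 12h, 0.13 at 18h, 0.04 at 4d), *Mybl2* (0.08 at 6h) and, at 7d, *Mcm5* (0.17), *Bmp4* (−0.96), *Synpo2* (−0.45) and *Pmp22* (−0.36). The ribosomal list passed at 24h, 36h, 48h and 3d but at none of these times with quantile normalization, nor with an estimated correlation (adjusted p between 0.32 and 0.51).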

Other observations

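The gene lists of this part were fixed before the data were examined, whereas the genes singled out below were chosen only after their values were seen, and no tests of explanations are reported here.

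Genes of cholesterol synthesis had list means at 6h and 12h of 1.36 and 1.83 in P10, 0.71 and 0.94 in 1999 and −0.17 and −0.19 in P6, relative to 0h of each culture. At 4d the means were 1.16, 1.27 and 1.33 in that order. Of the 19 genes 18 differed between cultures. The list passed with the preset correlation at 6h and 12h (camera adjusted p = 0.00092 and 5.8e-05) but not with an estimated correlation (adjusted p = 0.52 and 0.40).

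Genes of the Notch pathway did not pass as a list at any time (camera adjusted p between 0.16 and 0.98), with 0 of 12 members passing in limma, 1 to 3 at an unadjusted p under 0.05 and up to 3 with culture as a block. Genes of oxidative phosphorylation did not pass either (adjusted p between 0.37 and 0.99), with 0 of 25 members passing in limma, 0 or 1 at an unadjusted p under 0.05 and up to 2 with culture as a block, while 20 of 25 differed between cultures. In the interferon list 7 of 16 members differed between cultures.

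In P6, genes of the response to unfolded proteins and amino acid lack stood apart at 6h and 12h. *Ddit3* gave 1008 at 0h, 18686 at 6h, 27231 at 12h, 799 at 18h and 5240 at 36h. *Trib3* gave 623, 8662, 7904 and 56 from 0h to 18h, *Asns* 14358, 30068, 27115 and 2831, and *Chac1* 11541, 54158, 33784 and 2805. In 1999 *Ddit3* gave 1524 and 1364 at 6h and 12h and in P10 713 and 868, and *Chac1* gave 3292 and 2243 in 1999 and 3281 and 4085 in P10.

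Other probe sets of sex-linked genes were less far apart. The Y-linked *Kdm5d* had mean signals of 222 in 1999, 990 in P6 and 1362 in P10 by 1 probe set, 108, 339 and 299 by a second and 49, 62 and 68 by another, and *Uty* gave 46, 134 and 192. A second *Xist* probe set gave 283, 222 and 136.

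The labels print the same RNA concentration for 6h and 12h within each culture.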
